A study of Mus musculus with 6 samples.

How the data were processed

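Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 3 cell populations of the bone marrow of unimmunised Adig mice on the Balb/c background, isolated by flow sorting. Adig mice carry a GFP reporter of Aire, the autoimmune regulator that drives expression of tissue-restricted antigens in the thymus. Plasma cells were sorted as AireGFP-B220-CD138+TACI+, immature B cells as AireGFP-B220+CD138-TACI-IgM+ and pc-BMACs as AireGFP+B220-CD138+TACI+, per the labels. There were 2 libraries per population, each from 2000 to 15000 sorted cells per the labels' protocols, which do not state whether the libraries of a population came from separate animals. Sequencing used more than 1 Illumina platform, and which library ran on which was not stated.

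The authors deposited 1 peak list per library, with 5 columns and no header. Bowtie2 2.3.3, HOMER 4.10, bedtools and the mm10 build are named in the submitters' processing notes without their roles. The settings of peak calling and what was intersected to make each list are not given in the sources used here. The score column of the deposited lists holds the value 1000 in every row, so it ranked no peaks and was not used. Peaks were at least 150 bp wide and did not overlap within a list. The files give no read counts, so the depth of each library is unknown, only the presence of a peak could be compared between libraries, and no interval that needs a depth was computed. A region that was not called in a library is therefore not shown to be closed.

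Peaks of all 6 libraries were merged where they overlapped by at least 1 bp, which gave 69171 consensus regions, and a library was taken to have a region when at least 1 of its peaks overlapped it. For each comparison of 2 groups, group-only regions were those called in both libraries of one group and neither library of the other. Their count was set beside the same count for the 2 other ways of splitting the 4 libraries into pairs, which serves as the yardstick of replicate noise. With 3 splits the smallest two-sided exact p over libraries is 0.333, so no p over libraries is used. To place pc-BMACs between the other populations, regions called in 1 plasma cell library and absent from 1 immature B cell library were followed in the held-out libraries and in each pc-BMAC library, over all 4 choices, and the same was done with the 2 populations exchanged.

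Regions were assigned to genes of a RefSeq table of the GRCm38 assembly, the assembly that mm10 names. The plan was to use the nearest transcription start site, but the table gives no strand, so each region was assigned to the nearest protein-coding gene interval within 100 kb, and shares near promoters became shares within 1 kb of either gene end. In this way 65361 regions (94.5%) were assigned, to 15279 of 21900 protein-coding genes. The table gives no exons, so a region is described only as overlapping a gene or lying outside it. The planned comparison of 24 sequence motifs was not made, since no genome sequence was used here.

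The 14 gene lists were fixed before the data were examined: B cell identity, early B precursor, plasma cell, secretory pathway and unfolded protein response, antigen presentation and costimulation, activation and germinal centre, Aire regulation and NF-kB, homing and survival, dendritic cell and plasmacytoid dendritic cell, monocyte, macrophage and neutrophil, T, NK and innate lymphoid cell, erythroid and megakaryocyte, cell cycle, and housekeeping. For each list and direction, two-sided Fisher's exact tests compared the group-only regions assigned to list genes with all other assigned regions, with Benjamini-Hochberg adjustment over the 28 tests of a comparison and a threshold of 0.05. Odds ratios are given with their 95% intervals. The other assigned regions include those called only in the third population, which cannot be group-only. The odds ratio of a list therefore also depends on its share of such regions. Regions are the unit of these tests and regions of a gene are not independent, so the tests describe these libraries, not the variation between mice. As the alternative, each list's net number of group-only regions was compared with 10000 random lists of genes matched on their number of regions, by a two-sided permutation test adjusted over the 14 lists. The same Fisher's exact test was run for each of the 15279 genes, an addition made after the data were seen, with adjustment over all genes and, for genes of a fixed list, adjusted over the list alone. The limit on dependent regions of a gene holds for these tests as well, so their adjusted p can be too low.

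The rule for named genes was also fixed before the data were examined. It took, per comparison and direction, the 10 genes with most group-only regions, up to 3 members per gene list, and Aire, G6pc2, Prdm1, Xbp1, Irf4, Sdc1, Tnfrsf13b, Pax5, Ebf1, Ciita, Ptprc and Ighm. List members are named here for lists that passed the test, and 1 member that the rule names is not reported here. Rag2, Igll1, Gzma, Kit, Ell2, Bcl11a, Negr1, Il10, Phf14, Parn, Cd28, Ifng, Hba-a1, Hbb-bt, Gata1 and Alas2, and Il7r and Creb3l2 against immature B cells, were named after their values were seen.

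Alternatives fixed beforehand were a region counted as present only when peaks covered at least 50% of it, autosomes alone, leaving out each library in turn, gene bodies extended by 10 kb, matched random lists and a window of 2.5 kb at gene ends. Lists ranked by score could not be made, and the widest 34070 or 17035 peaks of each library stood in for them. For the gene lists, the rule of 50% coverage and the widest 17035 peaks were added after the data were seen. Leaving out regions within 1 kb of a gene end, comparing only the pair of libraries whose descriptions carry the same R number, and 2 further marker lists (NK cells, T cells) were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The tests were tested on simulated data with 65361 regions, in which the plasma cell, early B precursor, T, NK and innate lymphoid cell, and erythroid and megakaryocyte lists were enriched. In the comparison of pc-BMACs with plasma cells, an odds ratio of 4 was recovered in 80% to 100% of repeats and an odds ratio of 2 in 15% to 75%, with 0.417% and 0.208% of the other tests called. For plasma cells against immature B cells these shares were 80% to 100% and 10% to 45%, and for pc-BMACs against immature B cells 90% to 100% and 10% to 90%. Simulated regions were labelled independently of each other, unlike regions of a gene in the data. The share of other tests called can therefore be too low for these data.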

Results

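Open chromatin was profiled by ATAC-seq in plasma cells, immature B cells and pc-BMACs from mouse bone marrow, with 2 libraries per population. The pc-BMACs carry the plasma cell surface markers CD138 and TACI but express the Aire reporter, which the sorted plasma cells and immature B cells lack. The question was how the accessible chromatin of these cells compares with that of the other 2 populations. The plasma cell lists held 37272 ± 776 peaks (SD, n = 2), those of immature B cells 49088.5 ± 3613 peaks and those of pc-BMACs 36338.5 ± 3208 peaks. Peaks covered 21.9 and 21.5 Mb of the genome in plasma cells 1 and 2, 36.9 and 26.0 Mb in immature B cells 1 and 2, and 28.7 and 23.4 Mb in pc-BMACs 1 and 2. Median peak widths lay between 386.5 and 523 bp over the 6 libraries. Peaks within 1 kb of a gene end made up 30.3% ± 0.50 of the plasma cell lists, 24.4% ± 1.36 of the immature B cell lists and 30.9% ± 2.10 of the pc-BMAC lists (SD, n = 2 each), against 7.51% to 8.74% when the peaks of each list were shifted by 50 kb. Of the 69171 consensus regions, 20468 (29.6%) were called in all 6 libraries and 64.0% overlapped a gene.

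The open chromatin of pc-BMACs overlapped that of plasma cells more than that of immature B cells. The Jaccard index, the base pairs in both lists over those in either, averaged 0.593 between plasma cells and pc-BMACs (0.558 to 0.627 over 4 pairs of libraries), 0.515 between plasma cells and immature B cells (0.462 to 0.573) and 0.459 between immature B cells and pc-BMACs (0.430 to 0.474). The replicate pairs gave 0.748 for plasma cells, 0.652 for immature B cells and 0.728 for pc-BMACs, above every pair across populations. Each population also had regions of its own: 9904 regions were called in both immature B cell libraries alone, 3054 in both pc-BMAC libraries alone and 1041 in both plasma cell libraries alone. Plasma cells and pc-BMACs shared 2529 regions that neither immature B cell library had. Plasma cells and immature B cells shared 3377 regions that neither pc-BMAC library had, while immature B cells and pc-BMACs shared 736. This difference depended on the overlap rule: when peaks had to cover at least 50% of a region the counts were 1697 and 1263, and without pc-BMACs 2 they were 3706 and 1659. Patterns of 2 or 4 libraries that ran across the populations held at most 365 regions each.

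**Figure D1:**
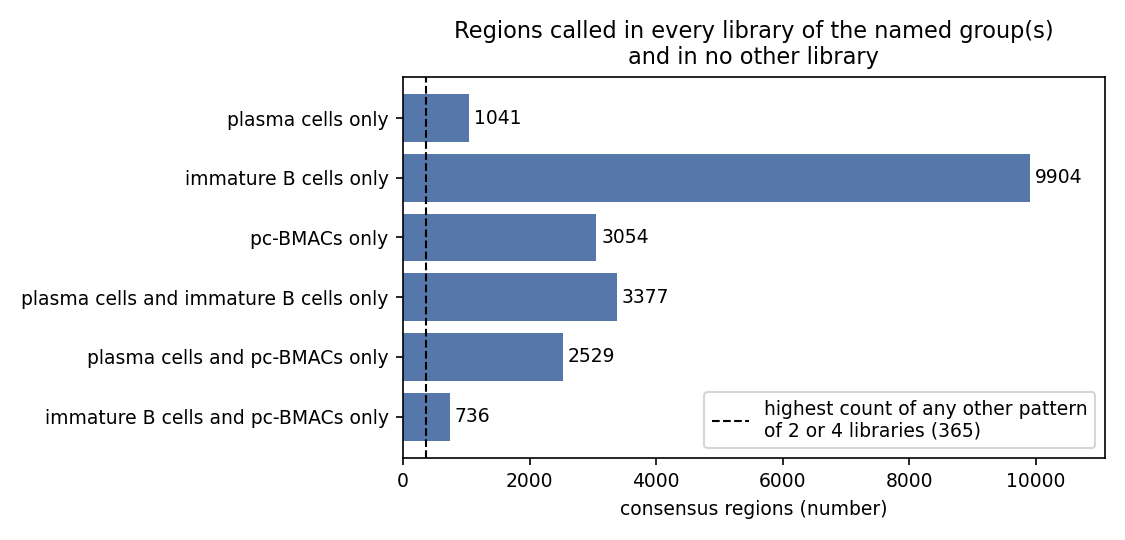
Bars give the number of consensus regions called in every library of the named populations and in no other library, from 736 for immature B cells with pc-BMACs to 9904 for immature B cells alone. The dashed line marks 365 regions, the highest count of any pattern of 2 or 4 libraries that does not follow the populations.

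Regions that set plasma cells apart from immature B cells were mostly called in pc-BMACs as well. Of the 5607 to 7941 regions called in 1 plasma cell library and absent from 1 immature B cell library, pc-BMACs 1 had 60.3% and pc-BMACs 2 had 56.6% (means over 4 choices of libraries). The held-out plasma cell library had 68.4% of them (59.9% to 76.5%) and the held-out immature B cell library 13.2% (6.92% to 20.5%). Of the 16292 to 22587 regions called in 1 immature B cell library and absent from 1 plasma cell library, pc-BMACs 1 had 16.1% and pc-BMACs 2 had 10.4%. The held-out immature B cell library had 74.1% of these (62.9% to 85.1%) and the held-out plasma cell library 13.3% (10.6% to 16.4%).

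**Figure D2:**
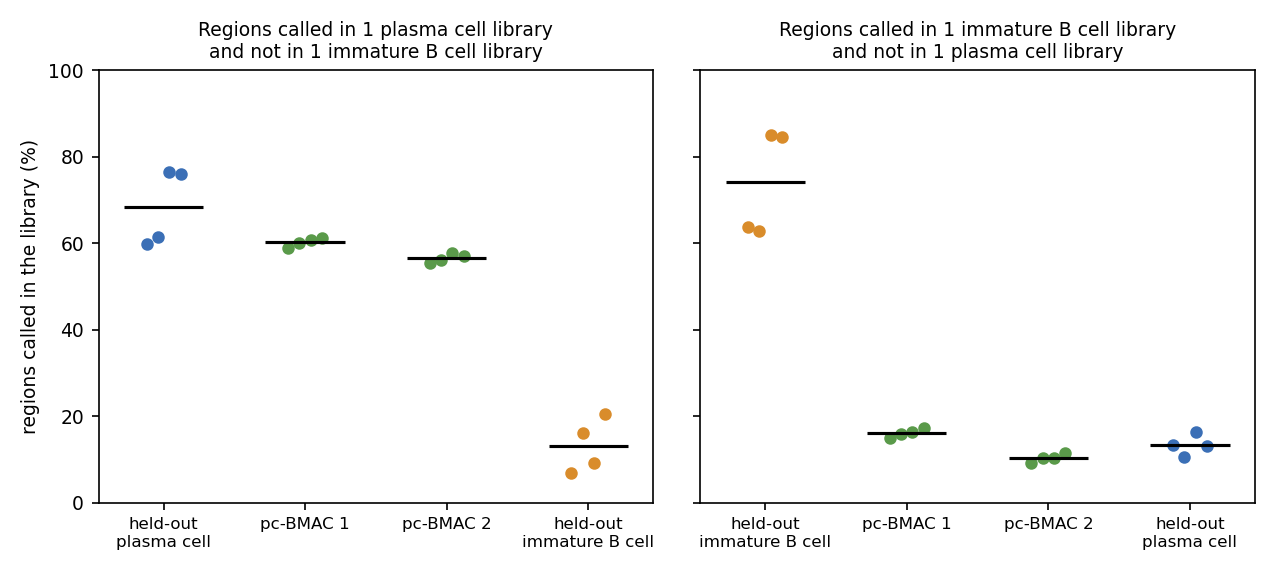
Points give the percent of regions called in each library, for regions chosen in 1 plasma cell and 1 immature B cell library, and black lines the mean over 4 choices. The pc-BMAC libraries had 60.3% and 56.6% of the plasma cell regions (left) and 16.1% and 10.4% of the immature B cell regions (right).

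Between pc-BMACs and plasma cells, 4 gene lists passed Fisher's exact test: plasma cell genes for regions of pc-BMACs, and early B precursor, T, NK and innate lymphoid cell, and erythroid genes for regions of plasma cells. With matched random gene lists the T, NK and innate lymphoid cell list alone kept its call. The background of the Fisher's exact tests included regions called in immature B cells alone, which cannot be group-only here. Regions called in both pc-BMAC libraries and neither plasma cell library numbered 4218, and 4739 regions showed the opposite pattern. The other splits of the 4 libraries gave 152 to 597 regions, and 23804 of the 50108 regions of the comparison were called in all 4 libraries. Of the plasma-cell-only regions, 3377 were called in both immature B cell libraries and 1041 in neither, while 736 of the pc-BMAC-only regions were called in both and 3054 in neither. These regions lay away from gene ends: 8.53% of the pc-BMAC-only regions were within 1 kb of one, against 26.3% of the other regions (Fisher's exact test, p = 3.35e-175). The other regions included those called in all 4 libraries, of which 41.9% lay within 1 kb of a gene end. Plasma-cell-only regions had a share of 8.53% too, so the low share does not set pc-BMACs apart. The counts and their balance depended on the peak rule and on which libraries were required. When peaks had to cover at least 50% of a region there were 6631 pc-BMAC-only and 3203 plasma-cell-only regions, and with the widest 34070 peaks 4303 and 4104. Without pc-BMACs 2 there were 8708 pc-BMAC-only regions, and without plasma cells 1 or 2 there were 7491 or 7387 plasma-cell-only regions.

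Plasma cell genes had more pc-BMAC-only than plasma-cell-only regions (36 and 13), which without depths does not show a gain in accessibility. Of 286 regions assigned to the plasma cell list, 36 were called in pc-BMACs alone of the 2 populations (odds ratio 2.17, 95% interval 1.49 to 3.10, Fisher's exact test, adjusted p = 0.000923), and 31 of the 36 were in neither immature B cell library. With matched random lists this call was lost (permutation test, adjusted p = 0.0777), as it was with the widest 17035 peaks (odds ratio 1.41, Fisher's exact adjusted p = 0.673). Of the 28 list genes with a region, 11 had more pc-BMAC-only than plasma-cell-only regions and 4 had fewer. Of these genes, 0 were enriched over all genes and 2 adjusted over the list alone, Creb3l2 and Fndc3b. Creb3l2, which encodes a stress-activated transcription factor of the endoplasmic reticulum, had 14 and 12 called regions in the 2 pc-BMAC libraries, 5 and 4 in plasma cells, and 4 and 4 in immature B cells. Among its pc-BMAC-only regions was one at chromosome 6, 37400686 to 37401481 (mm10), inside the gene. Fndc3b had 25 and 18 regions in pc-BMACs against 13 and 12 in plasma cells and 5 and 6 in immature B cells. Zbtb20, a transcription factor of long-lived plasma cells, had 4 pc-BMAC-only regions of 37. Ell2, an elongation factor that favours secretory immunoglobulin mRNA, had 16 and 14 regions in pc-BMACs and 10 and 7 in plasma cells.

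Plasma cells instead had more called regions at early B precursor genes. Of 198 regions of that list, 27 were called in plasma cells and not in pc-BMACs (odds ratio 2.24, 1.43 to 3.37, Fisher's exact test, adjusted p = 0.00408), and 23 of the 27 were in both immature B cell libraries. The call was lost with matched random lists (permutation test, adjusted p = 0.105) away from gene ends (odds ratio 1.85, adjusted p = 0.0645 by Fisher's exact test) and when peaks had to cover at least 50% of a region (1.61, adjusted p = 0.305). Of 19 list genes with a region, 10 had more plasma-cell-only regions and 3 fewer; 0 were enriched over all genes and 1, Erg, adjusted over the list alone. Erg, an ETS transcription factor of progenitors, had 8 and 8 regions in plasma cells, 26 and 17 in immature B cells, and 0 and 0 in pc-BMACs. The gene of the interleukin receptor chain Il7r had 3 and 4 regions in plasma cells, 8 and 6 in immature B cells and 0 and 0 in pc-BMACs. Every region of Erg and Il7r called in a plasma cell library was also called in both immature B cell libraries. Immature B cells carried over in the plasma cell sort could not be excluded as a source of such regions. Cd2 had 4 plasma-cell-only regions of 15. Both plasma cell and both immature B cell libraries, but neither pc-BMAC library, had a region at Rag2, which encodes a recombinase subunit (chromosome 2, 101624497 to 101625601), and 2 regions at Igll1, which encodes a surrogate light chain. Kit went the other way: it had 5 and 5 regions in pc-BMACs, 3 and 2 in plasma cells, and 1 and 0 in immature B cells.

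Genes of T, NK and innate lymphoid cells also had plasma-cell-only regions, 17 of 78 (odds ratio 3.94, 2.16 to 6.85, Fisher's exact test, adjusted p = 0.00031), and kept the call with matched random lists (permutation test, adjusted p = 0.0224). Of 17 genes with a region, 8 had more plasma-cell-only regions and 1 fewer; 0 were enriched over all genes and 1, Prf1, adjusted over the list alone. Prf1, which encodes the pore-forming protein of cytotoxic granules, had 3 and 3 regions in plasma cells, 1 and 1 in immature B cells and 0 and 0 in pc-BMACs, and 2 of them, such as chromosome 10, 61308179 to 61309167, were called in the plasma cell libraries alone. Il2rb had 3 plasma-cell-only regions of 7 and Tbx21 2 of 5, and the 1 region of Gzma was called in the plasma cell libraries alone. Of the 17 regions, 7 were in both immature B cell libraries and 7 in neither. A later list of NK cell markers had an odds ratio of 0.705 (0.141 to 2.16) and one of T cell markers 2.59 (1.49 to 4.25, Fisher's exact test, unadjusted p = 0.00069). Erythroid and megakaryocyte genes had 11 plasma-cell-only regions of 59 (odds ratio 3.24, 1.52 to 6.33, Fisher's exact test, adjusted p = 0.0107), led by Gfi1b with 3 and Ank1 with 2. Erythroid markers also set the plasma cell libraries apart from each other: Hba-a1, Hbb-bt, Gata1 and Alas2 each had 1 region, called in plasma cells 1 and in no other library. Of 17 genes with a region, 6 had more plasma-cell-only regions and 3 fewer, and 0 were enriched over all genes or adjusted over the list alone. This call was lost with matched random lists (permutation test, adjusted p = 0.253), with the widest 34070 peaks (odds ratio 2.21, Fisher's exact adjusted p = 0.286) and 17035 peaks (3.25, adjusted p = 0.163), without plasma cells 1 (2.19, adjusted p = 0.153) and without pc-BMACs 1 (2.35, adjusted p = 0.0846).

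With all 4 libraries the other lists did not pass the test. Group-only regions in pc-BMACs and in plasma cells numbered 12 and 31 of 359 for B cell identity, 9 and 1 of 107 for the secretory pathway and unfolded protein response, 8 and 9 of 145 for antigen presentation and costimulation, and 9 and 16 of 176 for activation and germinal centre. They numbered 9 and 6 of 133 for Aire regulation and NF-kB, 9 and 13 of 214 for homing and survival, 14 and 19 of 183 for dendritic cells, 2 and 10 of 102 for monocytes, macrophages and neutrophils, 2 and 0 of 68 for the cell cycle, and 3 and 3 of 72 for housekeeping genes. The lowest adjusted p among them was 0.0574 by Fisher's exact test, for the single plasma-cell-only region of the secretory list. In the only pair of these libraries whose descriptions share an R number, plasma cells 1 and pc-BMACs 2, the odds ratios were 1.86 for the plasma cell list, 2.04 for early B precursors, 2.84 for T, NK and innate lymphoid cells and 4.08 for the erythroid list (Fisher's exact test, adjusted p = 0.00185, 0.000737, 0.000737 and 3.05e-05). In this pair 2 further results passed: B cell identity genes had fewer pc-BMAC-only regions than other genes (16 of 359, odds ratio 0.437, adjusted p = 0.00235 by Fisher's exact test), and secretory genes fewer plasma-cell-only regions (5 of 107, 0.312, adjusted p = 0.0202). The pair includes plasma cells 1, the library with called regions at Hba-a1, Hbb-bt, Gata1 and Alas2, without which the erythroid list lost its call. What the R number stands for was not stated.

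**Figure D3:**
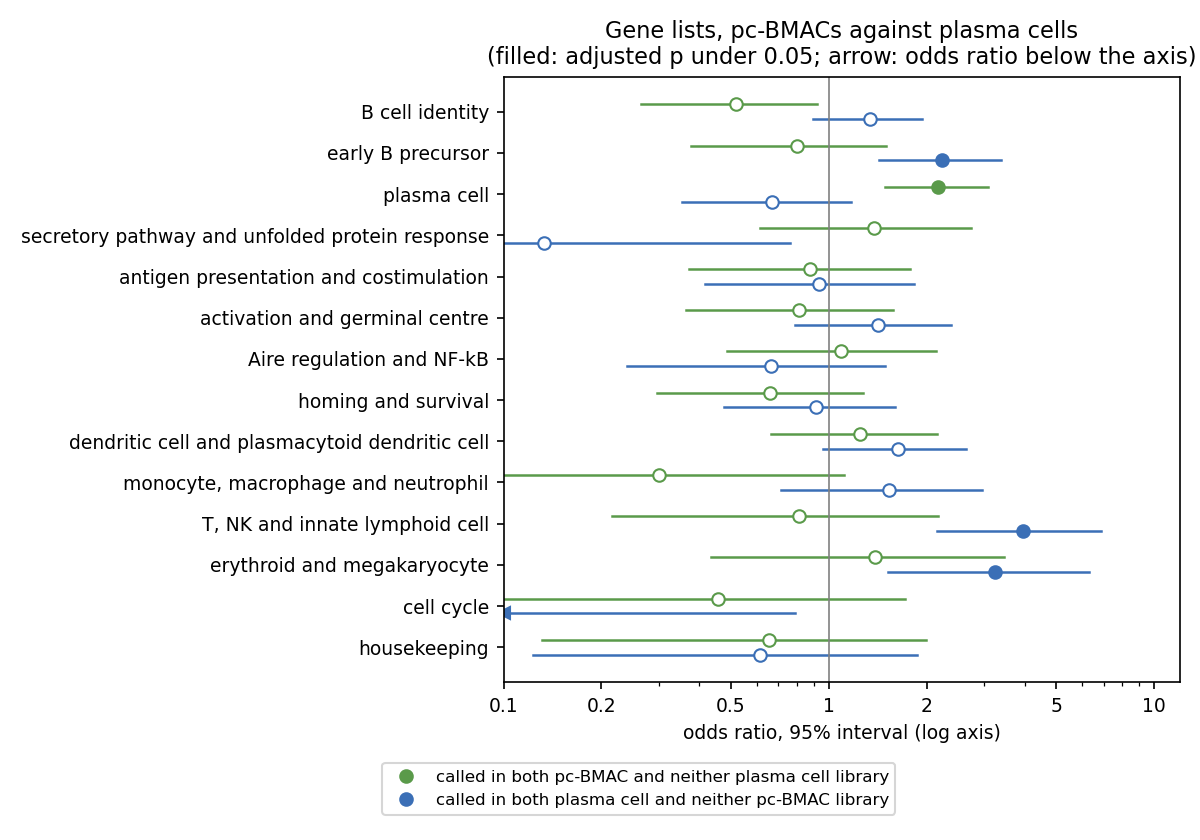
Points give the odds ratio for each gene list, with 95% intervals on a log axis, for regions called in both pc-BMAC and neither plasma cell library (green) and the reverse (blue). The plasma cell list stands at 2.17 in pc-BMACs, and the early B precursor, T, NK and innate lymphoid cell, and erythroid lists at 2.24, 3.94 and 3.24 in plasma cells.

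Single genes also held many group-only regions. The 10 genes with most pc-BMAC-only regions, 7 to 13 each, were Cacna1e, Hivep3, Foxp1, Rab11fip4, Lpp, Cpeb3, Fndc3b, Rbm47, Sik3 and Srbd1. Cacna1e, a voltage-gated calcium channel subunit (chromosome 1, 154390806 to 154884785), had 34 and 30 regions in pc-BMACs, 18 and 12 in plasma cells and 22 and 17 in immature B cells. It was 1 of 2 genes enriched over the 15279 genes tested (13 of 46 regions, Fisher's exact test, adjusted p = 0.041), with Negr1 (5 of 6 regions, adjusted p = 0.041); 317 had an unadjusted p under 0.05. The 10 genes with most plasma-cell-only regions, 6 to 9 each, were Tmem108, Pde4d, Pmepa1, Bach2, Erg, Osbpl3, Rad51b, Runx3, Vps8 and Atp10a, of which Bach2 and Rad51b turned to more pc-BMAC-only regions without pc-BMACs 2, and Rad51b also with peaks covering at least 50% of a region or with the widest 17035 peaks. Pmepa1, an inhibitor of TGF-beta signalling, was the 1 gene enriched in plasma cells, with 8 of 11 regions (Fisher's exact test, adjusted p = 0.000768; 318 genes had an unadjusted p under 0.05). It had 10 and 10 regions in plasma cells, 10 and 9 in immature B cells and 3 and 2 in pc-BMACs. Pde4d, a cyclic AMP phosphodiesterase, had 17 and 18 regions in plasma cells, 34 and 31 in immature B cells and 7 and 2 in pc-BMACs.

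**Figure D4:**
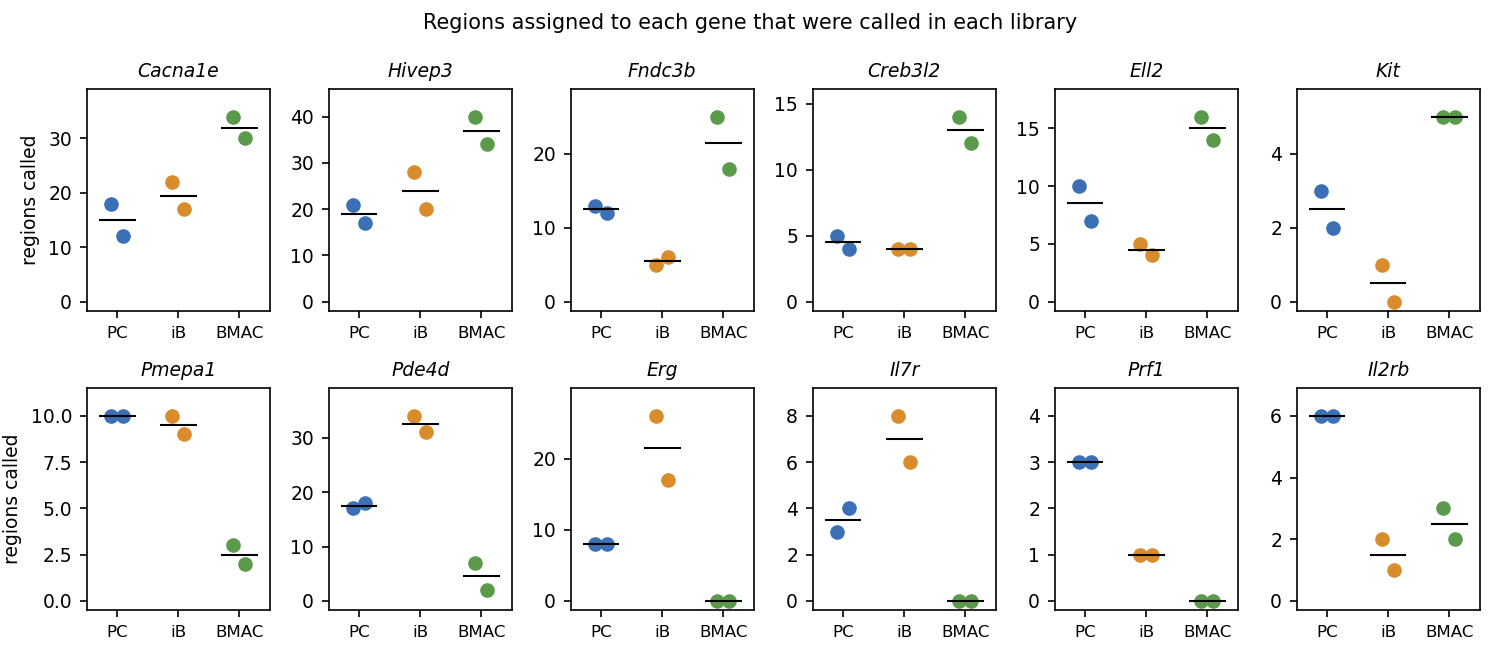
Points give the number of regions of each gene called in each library (PC plasma cells, iB immature B cells, BMAC pc-BMACs; n = 2 each) and lines the group means, with Ell2 and Kit named after their values were seen. Cacna1e had 34 and 30 regions in pc-BMACs against 18 and 12 in plasma cells, and Erg had 8 and 8 in plasma cells and 0 and 0 in pc-BMACs.

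Plasma cells differed from immature B cells in called regions in both directions. Immature B cells had 11803 regions that neither plasma cell library had, and plasma cells had 3942 that neither immature B cell library had, against 150 to 385 in the other splits. Regions called in all 4 libraries numbered 25402 of 62084. Within 1 kb of a gene end lay 8.30% of the plasma-cell-only and 6.31% of the immature-B-only regions. The excess of immature-B-only regions was not seen in lists of equal length: with the widest 34070 peaks of each library there were 4711 immature-B-only and 4634 plasma-cell-only regions, and with the widest 17035 there were 1813 and 1900. These lists also left out narrow peaks, and the share of each change was not tested. The immature-B-only count was 19589 without immature B cells 2, and the plasma-cell-only count was 6660 without plasma cells 2.

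Plasma cell genes had more plasma-cell-only regions than other genes, 40 of 286 (odds ratio 2.66, 1.85 to 3.74, Fisher's exact test, adjusted p = 7.99e-06). They had fewer immature-B-only regions than other genes, 25 of 286 (odds ratio 0.486, adjusted p = 0.00303 by Fisher's exact test). The shortage among immature-B-only regions was lost with the widest 34070 peaks (odds ratio 0.841, Fisher's exact adjusted p = 0.804) and 17035 peaks (0.948, adjusted p = 1). The net number of group-only regions of plasma cell genes (plasma cells minus immature B cells) exceeded that of matched random lists (permutation test, p = 0.0001, the smallest possible). Of 28 genes, 12 had more plasma-cell-only regions and 8 fewer; 0 were enriched over all genes and 4 adjusted over the list alone, Fndc3b, Zbtb20, Ern1 and Cd28. Fndc3b had 7 plasma-cell-only regions of 27. Ern1, the stress sensor that splices Xbp1 mRNA, had 5 of 17 and was called at 10 and 10 regions in plasma cells against 9 and 6 in immature B cells. Zbtb20 had 7 of 37, but its balance turned to immature B cells when peaks had to cover at least 50% of a region or without immature B cells 2.

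Homing and survival genes and antigen presentation genes also had plasma-cell-only regions. Of 214 homing and survival regions 26 were plasma-cell-only (odds ratio 2.26, 1.44 to 3.42, Fisher's exact test, adjusted p = 0.00318), with Cd44 at 5 of 22, Cd9 at 4 of 11 and the interleukin receptor chain Il6ra at 3 of 9; without immature B cells 2 Cd44 had more immature-B-only regions. Of 20 genes 8 had more plasma-cell-only and 10 more immature-B-only regions, and 0 were enriched over all genes or adjusted over the list alone. Of 145 antigen presentation and costimulation regions 18 were plasma-cell-only (odds ratio 2.31, 1.33 to 3.81, Fisher's exact test, adjusted p = 0.00715). Its plasma-cell-only regions included 3 of 6 at the costimulatory ligand gene Cd80, and 2 of 9 and 4 of 19 at the genes of the inhibitory ligands Cd274 and Pdcd1lg2, of which Pdcd1lg2 reversed without immature B cells 2, with peaks covering at least 50% of a region and with the widest 17035 peaks. Of 25 genes 5 had more plasma-cell-only and 9 more immature-B-only regions, and 0 were enriched over all genes or adjusted over the list alone. With matched random lists both calls were lost (permutation test, adjusted p = 0.181 for each). Without plasma cells 2 the adjusted p by Fisher's exact test was 0.0695 for homing and survival and 0.234 for antigen presentation, which also lost its call without immature B cells 1 (0.0764) and with the widest 17035 peaks (odds ratio 2.31, adjusted p = 0.0977).

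Genes of T, NK and innate lymphoid cells had 12 plasma-cell-only regions of 78 (odds ratio 2.97, 1.46 to 5.54, Fisher's exact test, adjusted p = 0.00682) and 3 immature-B-only regions (odds ratio 0.203, adjusted p = 0.00509 by Fisher's exact test, lost without plasma cells 2, immature B cells 1 or immature B cells 2 at 0.131, 0.102 and 0.127, and with the widest 17035 peaks at 0.479). Of 17 genes 7 had more plasma-cell-only regions and 2 fewer; 0 were enriched over all genes and 1, Il2rb with 4 of 7 regions, adjusted over the list alone. Prf1 had 2 of 3 and Cd247 1 of 6, which reversed for Cd247 when peaks had to cover at least 50% of a region. Erythroid and megakaryocyte genes had 11 plasma-cell-only regions of 59 (odds ratio 3.74, 1.75 to 7.31, Fisher's exact test, adjusted p = 0.00335), led by the anion exchanger Slc4a1 with 3 of 7, the transcription factor Tal1 with 2 of 3 and Ank1 with 2 of 8, and 1 immature-B-only region (odds ratio 0.0876, adjusted p = 0.00335 by Fisher's exact test, lost with the widest 34070 peaks at 0.652 and the widest 17035 at 0.636). Of 17 genes 6 had more plasma-cell-only regions and 0 fewer, and 0 were enriched over all genes or adjusted over the list alone. Both lists kept their calls with matched random lists (permutation test, adjusted p = 0.0014 and 0.0007). Both lost them when regions within 1 kb of a gene end were left out (odds ratios 2.34 and 2.88, Fisher's exact adjusted p = 0.127 and 0.0709) and with the widest 17035 peaks (2.39 and 1.22, adjusted p = 0.235 and 0.908). The remaining 9 lists did not pass, and the lowest adjusted p among them was 0.157 by Fisher's exact test. In plasma cells 2 and immature B cells 2, whose descriptions share an R number, the odds ratios were 2.60 for plasma cell, 3.14 for T, NK and innate lymphoid cell, 2.75 for erythroid, 1.91 for homing and 1.56 for antigen presentation genes (Fisher's exact test, adjusted p = 6.26e-08, 0.000715, 0.0123, 0.00896 and 0.23).

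The genes with most plasma-cell-only regions against immature B cells, 7 to 13 each, were Atxn1, Atg5, Mef2a, Dusp22, Fut8, St6gal1, Etv6, Fndc3b, Med27 and Tent5c. Of these, Dusp22 and St6gal1 had more immature-B-only regions without immature B cells 2. Atg5, an autophagy gene (chromosome 10, 44268322 to 44364299), had 16 and 16 regions in plasma cells and 9 and 8 in immature B cells. Tent5c, a poly(A) polymerase gene of plasma cells, had 14 and 12 regions in plasma cells, 5 and 4 in immature B cells and 15 and 15 in pc-BMACs. There were 5 enriched genes over all genes tested: Atg5 (10 of 25 regions, Fisher's exact test, adjusted p = 0.00931), Atxn1 (13 of 47, 0.0134), Mef2a (9 of 24, 0.0217), the cytokine gene Il10 (6 of 10, 0.0245) and Phf14 (6 of 11, 0.041); 318 had an unadjusted p under 0.05. The genes with most immature-B-only regions, 11 to 22 each, were Foxp1, Lpp, Pag1, Akap13, Arid1b, Foxn3, Pde4d, Ttc28, Xylt1 and Itga9, and 1 gene, Parn, was enriched (10 of 13 regions, Fisher's exact test, adjusted p = 0.0386; 348 had an unadjusted p under 0.05). Foxn3 turned to plasma cells with the widest 17035 peaks.

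More regions separated pc-BMACs from immature B cells, again with plasma cell genes on the pc-BMAC side and early B precursor genes on the other. There were 6765 pc-BMAC-only and 15860 immature-B-only regions, against 82 to 526 in the other splits, and 22356 of 65904 regions were called in all 4 libraries. The plasma cell list had 71 pc-BMAC-only regions of 286 (odds ratio 3.00, 2.26 to 3.94, Fisher's exact test, adjusted p = 1.32e-11) and 31 immature-B-only regions (odds ratio 0.432, adjusted p = 1.86e-05 by Fisher's exact test, lost with the widest 34070 peaks at 0.29 and the widest 17035 at 0.776). The pc-BMAC-only call held with matched random lists (permutation test, adjusted p = 0.0014). Of 28 genes 12 had more pc-BMAC-only regions and 8 fewer; 2 were enriched over all genes, Fndc3b (12 of 27 regions) and Zbtb20 (13 of 37), and 5 adjusted over the list alone, these with Ern1 (8 of 17), Creb3l2 (7 of 16) and Ell2 (7 of 19).

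Early B precursor genes had 69 immature-B-only regions of 198 (odds ratio 1.91, 1.41 to 2.58, Fisher's exact test, adjusted p = 0.000284). The call was lost with matched random lists (permutation test, adjusted p = 0.0826) away from gene ends (odds ratio 1.52, Fisher's exact adjusted p = 0.107) and with the widest 17035 peaks (1.96, adjusted p = 0.082). Of 19 genes 13 had more immature-B-only regions and 3 fewer; 1, Erg (16 of 27 regions), was enriched over all genes and 4 adjusted over the list alone, Erg, Il7r (6 of 8), Cd2 (8 of 15) and Igll1 (3 of 3). Arpp21 had 7 of 14. On the other side of this list, Kit had 4 pc-BMAC-only regions of 5 and was enriched adjusted over the list alone (Fisher's exact test, adjusted p = 0.0087). The remaining 12 lists did not pass, and the lowest adjusted p among them was 0.0762 by Fisher's exact test. In pc-BMACs 1 and immature B cells 1, whose descriptions share an R number, the odds ratio was 3.21 for the plasma cell list and 2.18 for early B precursors (Fisher's exact test, adjusted p = 1.41e-17 and 5.9e-07). The count of pc-BMAC-only regions was 10460 without pc-BMACs 2, and with the widest 34070 peaks there were 8017 pc-BMAC-only and 8026 immature-B-only regions. With the widest 17035 peaks there were 2938 pc-BMAC-only and 2840 immature-B-only regions.

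Among single genes, 22 were enriched in pc-BMACs and 16 in immature B cells (Fisher's exact test over all genes; 404 and 621 at an unadjusted p under 0.05). The 10 with most pc-BMAC-only regions, 12 to 18 each, were Atxn1, Cacna1e, Foxp1, Hivep3, Cpeb3, Etv6, Zbtb20, Fndc3b, Med27 and Tmem154, and 8 of them were enriched. The 10 with most immature-B-only regions, 15 to 23 each, were Foxp1, Pde4d, Nav2, Lpp, Pag1, Tmem108, Bach2, Erg, Itga9 and Zcchc7, and 6 of them were enriched. Foxp1, a transcription factor gene with 99 regions, stood in both sets, and its balance turned to pc-BMACs without pc-BMACs 2; that of Lpp turned with the widest peaks. Pde4d had 23 immature-B-only regions of 37 and the cytokine gene Ifng 13 of 15 (adjusted p = 0.00135 for each by Fisher's exact test).

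Genes named beforehand had regions in every population, with G6pc2 as the exception. The 24 regions near Prdm1, the plasma cell repressor of the B cell programme, were called at 12 and 11 sites in plasma cells, 14 and 16 in immature B cells and 13 and 12 in pc-BMACs. Xbp1 had 6 and 6 regions in plasma cells, 5 and 4 in immature B cells and 6 and 6 in pc-BMACs, and the region at chromosome 11, 5523753 to 5528807, which overlaps the gene, was called in both plasma cell and both pc-BMAC libraries and in neither immature B cell library. Near Irf4, a region at chromosome 13, 30736498 to 30737776 was called in plasma cells and immature B cells but not in pc-BMACs, one at 30738404 to 30738803 in pc-BMACs alone, and one at 30765853 to 30767951 in immature B cells alone. Sdc1, which encodes CD138, had 9 and 9 regions in plasma cells, 11 and 8 in immature B cells and 6 and 7 in pc-BMACs, and Tnfrsf13b, which encodes TACI, had 7 or 8 regions in every library. Pax5, which holds B cell identity, had 10 and 8 regions in plasma cells, 15 and 14 in immature B cells and 7 and 5 in pc-BMACs. Ebf1 had 25 and 29, 33 and 32, and 24 and 18 regions in the same order, where plasma cells passed immature B cells in group-only regions with the widest 34070 peaks, and Bcl11a 12 and 13, 28 and 21, and 10 and 7. Ciita, the MHC class II transactivator, had 5 and 5 regions in plasma cells, 7 and 8 in immature B cells and 5 and 3 in pc-BMACs, Ptprc 12 and 9, 16 and 14, and 14 and 9, and Ighm 1 or 2 in every library.

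Aire itself had 2 regions in each of the 6 libraries. The first, chromosome 10, 78025473 to 78042727, reached the gene only through 1 peak of plasma cells 2, and in the other 5 libraries its peaks lay outside the gene. The second, 78043277 to 78047927, overlapped the gene at its higher coordinate, 78043610, and also lay within Dnmt3l. Without strands, the gene table does not say whether this is where transcription of Aire starts or ends. Peaks covered 95.1% of the gene in plasma cells 2 and 1.87% to 2.46% in the other libraries, and neither region separated the reporter-positive pc-BMACs from the other cells. G6pc2, a pancreatic islet gene, had 1 region, at chromosome 2, 69226553 to 69227048, called in plasma cells 2 and pc-BMACs 2. Peak lists cannot tell a gene from copies of its sequence in a transgene. The construction of the reporter transgene is not stated in the sources used here, so the origin of this region was not tested. Around Aire, called peaks covered an unusually high share of the sequence in all 6 libraries. The stretch of 180 kb between 77960001 and 78140000 of chromosome 10 holds Cfap410, Pfkl, Aire, Dnmt3l, Icosl and part of Trpm2. Called peaks covered 18.6% and 66.4% of this stretch in plasma cells, 20.5% and 24.9% in immature B cells, and 17.9% and 28.8% in pc-BMACs. Its bounds were set by the coverage itself, as the run of 20 kb bins around Aire with at least 5% called in all 6 libraries. The rest of a 900 kb stretch around Aire was covered at 2.89% to 5.75%, a contrast that this choice of bounds favours. The widest peak there had 37127 bp in plasma cells 2, 11483 bp in immature B cells 2 and 12559 bp in pc-BMACs 2, and 3826, 5002 and 4421 bp in plasma cells 1, immature B cells 1 and pc-BMACs 1, and region counts of Aire and Icosl carry that limit.

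**Figure D5:**
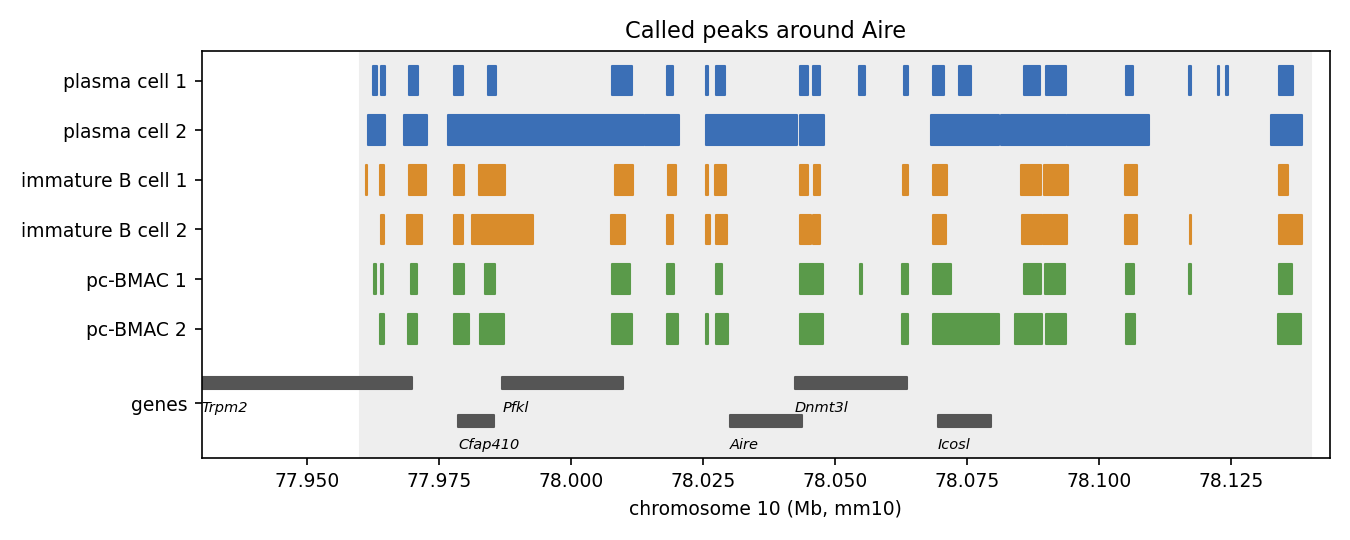
Coloured blocks are called peaks in each of the 6 libraries along chromosome 10 (Mb, mm10), dark blocks are genes, and grey shading marks 77960001 to 78140000. Plasma cells 2 had the broadest coverage of the shaded stretch, 66.4%, and the other 5 libraries 17.9% to 28.8%.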

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

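The alternatives with the widest peaks, the rule of 50% coverage for gene lists, and those with regions over 1 kb from a gene end and libraries sharing an R number were chosen after the data were seen; the others were fixed before the data were examined. Depth was unknown and scores were constant, so lists ranked by score were not run, nor were motif results. No paired analysis was possible because a region called in both libraries of one group and neither of the other meets that rule within each of the 2 pairs however the 4 libraries are paired, and because the R numbers of the descriptions, which part from the replicate numbers of the titles, are shared by 1 pair of libraries per comparison. Within that pair alone, which loosens the rule by construction, 6525 regions were called in pc-BMACs 2 and not plasma cells 1 and 9549 the other way, 6413 in plasma cells 2 and not immature B cells 2 and 16292 the other way, and 10968 in pc-BMACs 1 and not immature B cells 1 and 24383 the other way. The odds ratio of a gene list called in the comparisons kept its direction when recomputed with 50% coverage, the widest 34070 and 17035 peaks, extended gene bodies, regions over 1 kb from a gene end and each library left out, in 108 values past the threshold and in 27 no longer past it. Of the differences for named genes, 543 recomputed values moved by less than the replicate spread, 209 moved further and 18 reversed.

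When peaks had to cover at least 50% of a region, the pc-BMAC-only regions against plasma cells numbered 6631, pc-BMACs had 53.0% of the plasma cell regions, and the differences in group-only regions reversed to 6 for Rad51b (pc-BMACs minus plasma cells) and, as plasma cells minus immature B cells, to -1 for Cd247, -2 for Pdcd1lg2 and -1 for Zbtb20; the cause was not tested. With the widest 34070 peaks the immature-B-only regions fell to 4711 against plasma cells and 8026 against pc-BMACs, and the differences reversed to 5 for Ebf1 (plasma cells minus immature B cells) and 1 for Lpp (pc-BMACs minus immature B cells). With the widest 17035 peaks, which hold fewer regions by construction, the counts were 1533 pc-BMAC-only and 1540 plasma-cell-only, 1900 plasma-cell-only and 1813 immature-B-only, and 2938 pc-BMAC-only and 2840 immature-B-only regions in the 3 comparisons. In the same lists pc-BMACs had 64.4% of the plasma cell regions, and Rad51b reversed to 1, Foxn3 to 1, Pdcd1lg2 to -1 and Lpp to 2; the cause was not tested.

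With matched random gene lists, 1, 3 and 1 lists passed in the comparisons of pc-BMACs with plasma cells, plasma cells with immature B cells and pc-BMACs with immature B cells, against 4, 5 and 2 by Fisher's exact test. Between plasma cells and immature B cells 8 lists passed when peaks had to cover at least 50% of a region, and between pc-BMACs and immature B cells 5 passed with the widest 17035 peaks. With regions over 1 kb from a gene end, 3 lists passed between plasma cells and immature B cells and 1 between pc-BMACs and immature B cells; the cause was not tested. The Jaccard index within groups was 0.767 over consensus regions against 0.709 over base pairs, and 34.4% of peaks lay within 2.5 kb of a gene end against 28.5% within 1 kb, a wider window by construction.

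Leaving out each library in turn loosens the rule for group-only regions by construction and gave 5102 to 8708 pc-BMAC-only regions against plasma cells (8708 without pc-BMACs 2), 5252 to 7491 plasma-cell-only regions against pc-BMACs (7491 and 7387 without plasma cells 1 and 2), 4287 to 6660 plasma-cell-only regions against immature B cells (6660 without plasma cells 2), 13776 to 19589 immature-B-only regions against plasma cells (19589 without immature B cells 2), and 7133 to 10460 pc-BMAC-only regions against immature B cells (10460 without pc-BMACs 2). Lists passing between plasma cells and immature B cells ranged from 3 without plasma cells 2 to 6. The difference in group-only regions ranged from -12 to 3 for Bach2 and -2 to 3 for Rad51b (pc-BMACs minus plasma cells), and -13 to 3 for Foxp1 (pc-BMACs minus immature B cells), each reversed without pc-BMACs 2. As plasma cells minus immature B cells it ranged from -1 to 3 for Cd44, -2 to 5 for Dusp22, -2 to 3 for Pdcd1lg2, -2 to 3 for St6gal1 and -1 to 5 for Zbtb20, each reversed without immature B cells 2; the cause was not tested.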

Other observations

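The tests of T cell markers and those of the peaks around Aire were chosen after the results were seen. Plasma cells shared 3377 regions with immature B cells that neither pc-BMAC library had, and pc-BMACs shared 736 with immature B cells, a ratio of 4.59. Fewer weak peaks in the pc-BMAC lists could not be excluded as the cause. With the widest 34070 peaks of each library the ratio was 6.71. That test does not decide, since peaks were ranked by width, not strength, and 34070 is the full list of pc-BMACs 2. Median peak widths averaged 506 bp in pc-BMACs and 409 bp in plasma cells. The ratio was 2.23 without pc-BMACs 2 and 1.34 when peaks had to cover at least 50% of a region. Immature B cells carried over in the plasma cell sort could not be excluded, since of the regions called in both immature B cell and neither pc-BMAC library both plasma cell libraries had 1.89% of the narrowest 10% and 61.1% of the widest 10%. In neither plasma cell library were 22.9% of the widest 10%, but a small carry-over could also miss regions, so this does not decide. For comparison, regions called in both immature B cell and neither plasma cell library were followed in pc-BMACs. Both pc-BMAC libraries had 3.22% of the narrowest 10% of these and 9.92% of the widest 10%. The B220- gate selects against immature B cells, but sort purity was not examined here. No biological explanation was tested, and the B cell identity list did not pass between plasma cells and pc-BMACs with all 4 libraries (Fisher's exact test: plasma-cell-only 31 of 359 regions, odds ratio 1.34, adjusted p = 0.377; pc-BMAC-only 12 of 359, 0.518, adjusted p = 0.0925), though in the pair with the same R number its pc-BMAC-only odds ratio was 0.437 (adjusted p = 0.00235).

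Regions of T, NK and innate lymphoid cell genes were called in plasma cells and not in pc-BMACs with an odds ratio of 3.94. A separate NK marker list, 2 of whose genes another list holds, had an odds ratio of 0.705 (0.141 to 2.16, Fisher's exact p = 0.799). Its upper bound lay below 3.94, the result predicted beforehand if NK cells were not carried over in the plasma cell sort. NK cells are not excluded by it, since the interval reaches 2.16 and only 15 of the 20 list genes had a region. The list leaves out Prf1, Gzma, Il2rb and Tbx21, so the regions of these genes were not tested by it. No region was assigned to Ncr1, Nkg7 or Gzmb in the 6 libraries. The same was true of the cell cycle gene Foxm1, so lack of an assigned region does not show a closed locus. T cells cannot be told apart from a difference within plasma cells: a T cell marker list, 7 of whose genes another list holds, had an odds ratio of 2.59 (1.49 to 4.25, Fisher's exact p = 0.00069), but 16 of its 19 regions were also in both immature B cell libraries. Over regions called in the plasma cell libraries alone the odds ratio was 6.49 (2.51 to 14.1) for the first list, 1.08 (0.129 to 4.00) for T cell and 0 (0 to 3.95) for NK cell markers. Bcl11b, Themis and Cd8a had 0 assigned regions in the 6 libraries, which likewise does not show closed loci. The CD138+TACI+ gate selects against T and NK cells, but sort purity was not examined here. Plasma cells 1, sorted by the same gate, had called regions at Hba-a1, Hbb-bt, Gata1 and Alas2.

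Around Aire, called peaks covered an unusual share of the sequence in all 6 libraries. Open chromatin in reporter-positive cells as the cause is argued against by the 4 AireGFP-negative libraries, in which the window of 213.588 kb ranked at the 99.93rd percentile or above. A window dense in genes is argued against by its rank among 1076 windows with at least 11 gene ends, at the 99.44th percentile or above. Extra genomic copies of the locus, carried by the reporter transgene, stay open: the window ranked at the 99.87th percentile or above in all 6 libraries, but this high coverage prompted the explanation and is no test of it, the construction of the transgene is not stated in the sources used here, and copy number was not analysed here. Plasma cells 2 stood apart, with 66.4% of the 180 kb called against 17.9% to 28.8% in the other libraries, and was 1 of the 2 libraries with the G6pc2 region, the other being pc-BMACs 2.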
